A study of Homo sapiens with 12 samples.

How the data were processed

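Total RNA from PEO1R ovarian cancer cells was extracted with a phenol reagent, amplified to biotin-labelled cRNA and hybridised to Illumina human expression bead arrays, per the labels, in 4 groups of 3 biological replicates. The series deposits 2 tables: a table without normalization and a table of processed values. Per the file headers, the first gives for each of 47231 probes and 12 arrays a mean bead signal, an intensity that was not normalized between arrays, a detection score, and the number of beads behind the value. The detection score deposited is 1 minus the detection p, as its rise with signal shows, and the bead numbers, a count of another kind deposited beside the signals, were used only to check the arrays; 60 other columns were not used. The second table holds the authors' processed values on a log2 scale. How the authors made them is not given in the sources used here; their distributions are nearly identical on all arrays (medians 7.20781 to 7.20837), the ranks of probes on each array match the first table (0 probes differ), and they follow log2 signal with a slope of 0.413 to 0.528 at a log2 signal of 6 and 0.947 to 1.02 at 10, so that small signals are compressed.

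Values were made from the first table with R 4.3.3 and limma 3.58.1. Signals were background-corrected with neqc, which estimates the background from the detection p where a table holds no control probes, with an offset of 16, quantile normalized and taken to log2. Of the probes, 30113 carry exactly 1 gene symbol in the annotation, 8 carry several and 17110 none; the last 2 kinds were left out. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept (17861), and for each of 13171 genes the probe with the highest mean represented the gene; 3643 genes had more than 1 kept probe. Identifiers are the gene symbols of the array's annotation, and genome positions are not given, since the arrays measure transcripts through probes. limma was fitted with 1 mean per group over all 12 arrays (8 residual degrees of freedom), with empirical Bayes moderation, and p-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05. The 7 comparisons are those of each treated group with control, of the combination with each single treatment, the interaction (combination minus MEK inhibition minus Src inhibition plus control) and MEK inhibition with Src inhibition; all tests are two-sided.

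For named genes whose probe was undetected on 1 or more arrays of the dim group and that passed by over 1 on the log2 scale, or undetected on all of its arrays, a lower bound of the fold is given: the bright group's mean against the dim group's mean of, on each array, the higher of the lowest detected signal and the probe's own signal. The number of replicates limits the precision, with a median SE of 0.105 for a comparison of groups and 0.148 for the interaction. In data simulated with this design, 50 of 13171 genes changed at each size. The fit recovered 6% at a log2 change of 0.3, 50% at 0.5 and 100% at 1 and 2, and 5 of 133 called were unchanged. The cut is looser where more genes pass, as here, so these rates do not carry over.

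Gene lists were tested with camera, with a preset correlation of 0.01, on the log2 fold changes of 36 of 39 lists, those with at least 5 measured genes; adjusted p-values are over the 36 lists of a comparison. The lists cover signalling (ERK output, immediate early genes, receptor kinases and adaptors, Src family and MAPK cascade, YAP and TEAD, actin and SRF, WNT, TGF-beta and SMAD, NF-kB and cytokines, interferon), adhesion and identity (focal adhesion and integrins, epithelial junctions, mesenchymal genes, ovarian stem-like cells and carcinoma), growth (G1/S, G2/M, cell cycle brakes, DNA repair, ribosome biogenesis and MYC, ribosomal proteins), death and survival, p53, metabolism and stress (cholesterol, fatty acids, glycolysis and hypoxia, oxidative phosphorylation, ATF4, NRF2, ER chaperones, heat shock, lysosome and autophagy), antigen presentation, housekeeping genes, and markers of melanocytes, fibroblasts, leukocytes and endothelium. They were written from general knowledge, and some genes stand in more than 1 list. With a correlation estimated from the data, 9 of the 13 lists called under MEK inhibition, 12 of 17 under Src inhibition, 8 of 14 in the combination, 5 of 15 and 7 of 11 in the combination against MEK and Src inhibition, 9 of 11 in the interaction and 10 of 19 between the single treatments were called.

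The lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined, except the alternatives for the overlap of the single treatments, which were added later. The rule names, in each comparison with control, the 6 largest rises and 6 largest falls among genes that passed and whose 3 treated arrays all lay on 1 side of the 3 controls, and in the other comparisons the 4 largest each way (for the interaction without the condition on arrays), leaving out uncharacterised symbols. One result under this rule is not reported here. The rule adds up to 4 genes with the smallest adjusted p from each list described, and 16 anchor genes given in every comparison: DUSP6, SPRY4, ETV4, ETV5, CCND1, EGR1, MYC, FOSL1, CDKN1A, CDKN1B, BCL2L11, SRC, MAP2K1, INSR, NF1 and ALDH1A1. The alternatives were no background correction, background correction without the detection p, centring on array medians, the authors' values, no filter on dim probes, a detection p under 0.01, the mean of a gene's probes, only the groups compared, a moderated variance with a trend and robust prior, array weights, a block for the replicate number, each array left out in turn, a fold of at least 2, and for lists an estimated correlation and limma's fry. Replicate numbers do not pair the arrays: after removal of group means, 5 of 12 arrays correlated best with an array of their own number, so the block stands as an alternative only. No slide, chip or date is given in the sources used here, so no batch could be fitted.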

Results

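Transcript levels were measured in PEO1R cells, an established human ovarian cancer cell line, on 12 Illumina bead arrays that carry 47231 probes. The cells fell into 4 groups of 3 biological replicates: control cells, cells given a MEK inhibitor, cells given a Src inhibitor, and cells given both (the combination). MEK is the kinase that activates ERK in the MAP kinase cascade, and Src is a tyrosine kinase that acts downstream of integrins and growth factor receptors. The inhibitors, their doses and the time of exposure are not given in the sources used here, and a treatment label calls the cells melanoma cells while the other labels name the ovarian line. On each array 21413 to 22516 probes (45.3% to 47.7%) were detected, the median signal was 74.7 to 86.4 and the mean signal 458 to 540 intensity units, and a median of 22 to 23 beads lay behind each probe value. The 13171 genes tested are those with a detected probe, and 3 arrays per group limit the precision of every value. Changes below are log2 fold changes ± standard error (SE) with 3 arrays in each group, "rose" and "fell" are used of genes that passed limma's test at an adjusted p under 0.05, and list tests are camera's, with medians on the log2 scale. Counts over the list alone, with p adjusted within that list, are given where they differ from the counts over all genes.

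Markers of ovarian carcinoma and of 4 other cell types were read to describe the cells. Of 20 ovarian carcinoma markers on the array, 17 were detected on all 12 arrays and 2, FOLR1 and SOX17, on none, and their median control level was 9.27 on the log2 scale, against 7.71 over all tested genes. The median control level was 4.96 for 11 melanocyte markers, of which 5 (TYR, TYRP1, MLANA, SOX10 and S100B) were detected on no array and 3 (MITF, MC1R and GPR143) on all 12. It was 4.76 for 10 fibroblast markers, 4.84 for 11 leukocyte markers and 4.65 for 9 endothelial markers, with 5, 6 and 5 of them detected on no array. Among these 41, CD68 (10.13), THY1 (10.09), CD14 (8.85) and GPR143 (8.73) lay above the median of tested genes, and levels of different probes share no common scale. Markers named here by their detection alone were picked out after their levels were seen.

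The first principal component of the tested genes held 64.7% of the variance and ordered the groups as control (-41.2 to -42.6), Src inhibition (-6.75 to -9.46), MEK inhibition (12.6 to 14.4) and combination (35.6 to 37.8). The second, with 12.8%, set MEK inhibition (-20.4 to -22.0) apart from Src inhibition (8.21 to 13.2) and the combination (9.62 to 11.5). Replicates of a group correlated across genes, which are not independent, with r between 0.991 and 0.996. Src inhibition replicate 3 stood apart from the other Src inhibition arrays on the third component, at -24.5 against -4.02 and -4.64, and 25 of its genes lay over 2-fold from the mean of the other replicates, against 0 to 9 genes on the other 11 arrays.

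**Figure D1:**
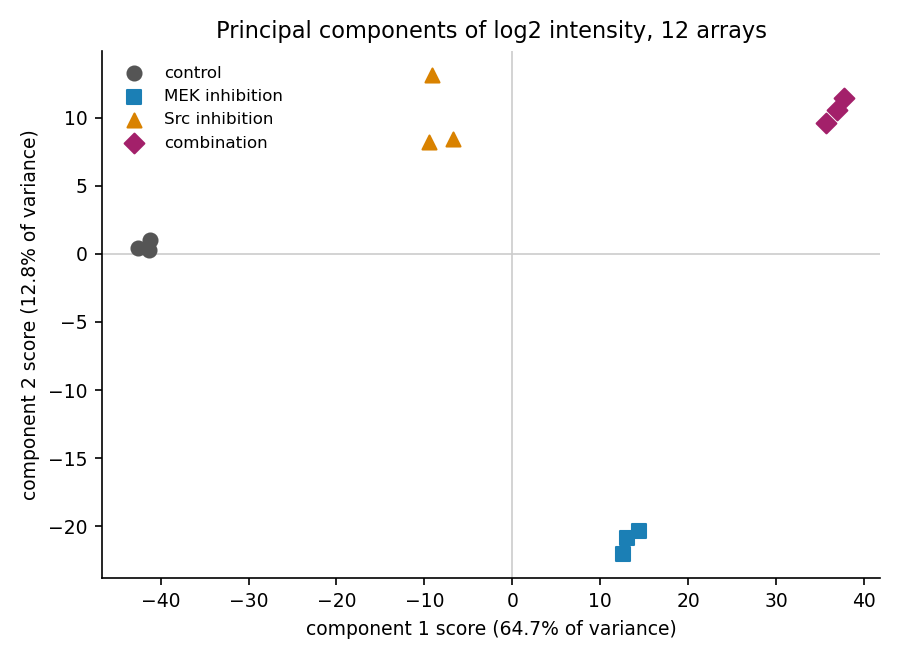
Each point is 1 of the 12 arrays, placed by its scores on the first (horizontal) and second (vertical) principal components of the log2 levels of 13171 genes, coloured by group. The 3 controls lie at -41.2 to -42.6 on the first component.

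MEK inhibition was compared with control to ask which transcripts changed when MEK alone was inhibited. The immune checkpoint ligand VTCN1 rose 25.3-fold (log2 change 4.66 ± 0.10, adjusted p = 2.12e-11). The matrix metalloproteinase MMP7 rose 17.7-fold (4.14 ± 0.11), the epithelial keratin KRT13 15.5-fold (3.96 ± 0.081) and the GABA-A receptor subunit GABRP at least 12.8-fold, and the pregnancy-specific glycoproteins PSG7 and PSG4 rose 14.4-fold (3.85 ± 0.13) and 13.2-fold (3.72 ± 0.086). The secreted proteoglycan ESM1 (endocan) fell 24.9-fold (log2 change -4.64 ± 0.078, adjusted p = 2.96e-12), the hyaluronan synthase HAS3 fell at least 11.8-fold and the membrane-bound ubiquitin ligase MARCHF4 fell 6.18-fold (-2.63 ± 0.13). Bounds ("at least") stand where the probe was not detected on every array of the dim group, GABRP being detected on 1 of 3 control and HAS3 on 1 of 3 treated arrays. PHLDA1, a target of ERK signalling, fell 6.18-fold (-2.63 ± 0.082), FOSL1, a FOS-family transcription factor, 5.39-fold (-2.43 ± 0.15) and the calcium-binding protein CALB2 (calretinin) 5.26-fold (-2.40 ± 0.12). Of 25 genes of the ERK output list, 3 rose, 18 fell and 4 did not pass (over the list alone, 4 rose and 18 fell; median -0.81, adjusted p = 1.27e-07). Other probes gave smaller changes for CALB2 (-0.22), PHLDA1 (-1.17), DUSP6 (-0.76) and ETV5 (-1.36). The ERK phosphatases DUSP4, DUSP5 and DUSP6 fell, with log2 changes of -2.27 ± 0.094, -1.74 ± 0.073 and -2.10 ± 0.17, the ETS factors ETV4 and ETV5 changed by -2.21 ± 0.13 and -2.39 ± 0.12, and the pathway inhibitor SPRY4 by -1.44 ± 0.10. EGR1 (-0.73 ± 0.089), MYC (-0.40 ± 0.090), the cyclin CCND1 (-0.77 ± 0.068) and MAP2K1, which encodes MEK itself (-0.35 ± 0.076), also fell.

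Genes of cell division fell together with MEK inhibition. All 34 measured genes of the G2/M and mitosis list fell (median -0.99, adjusted p = 1.72e-19), among them the mitotic cyclin CCNA2 (-1.25 ± 0.065), the mitotic motor CENPE (-1.27 ± 0.068) and the checkpoint kinase BUB1 (-1.11 ± 0.070). Of 36 genes of G1/S and DNA replication, 35 fell and 1 did not pass (median -0.78, adjusted p = 1.11e-16). UHRF1 had -1.31 ± 0.076, GINS4 -1.18 ± 0.085 and CDC45 -1.09 ± 0.073. DNA repair genes followed: of 21, 17 fell and 4 did not pass (median -0.82, adjusted p = 3.21e-08), such as FANCB (-1.29 ± 0.11) and EXO1 (-1.21 ± 0.085). Of 31 genes of ribosome biogenesis and MYC targets, 29 fell and 2 did not pass (median -0.67, adjusted p = 9.08e-12), including NOLC1 (-1.08 ± 0.063) and DKC1 (-0.77 ± 0.067). Among 22 cell cycle brakes, 11 rose, 3 fell and 8 did not pass (median 0.28, adjusted p = 0.0111; adjusted p = 0.0831 with an estimated correlation). KLHL24 had 1.88 ± 0.092, TXNIP 1.42 ± 0.10 and CITED2 1.36 ± 0.081. The cyclin-dependent kinase inhibitor CDKN1B changed by 0.38 ± 0.11 (adjusted p = 0.0163); the call ended with median centring (0.20) and without control replicate 2 (0.35) or 3 (0.31). CDKN1A had 0.16 ± 0.12 (adjusted p = 0.316).

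Lists of epithelial identity, immune display and degradation rose with MEK inhibition. Of 24 epithelial junction genes, 18 rose and 6 did not pass (median 0.57, adjusted p = 7.86e-06). The epithelial transcription factor ELF3 had 1.04 ± 0.10 and the desmosomal genes PKP2 and DSC2 0.86 ± 0.086 and 0.80 ± 0.077. Of 18 ovarian carcinoma markers, 11 rose, 3 fell and 4 did not pass (median 0.66, adjusted p = 0.0136; adjusted p = 0.0523 with an estimated correlation), among them the mucin MUC16 (2.25 ± 0.13) and mesothelin, MSLN (1.44 ± 0.070). Of 28 genes of lysosome and autophagy, 19 rose, 1 fell and 8 did not pass (median 0.47, adjusted p = 7.09e-06), such as the lysosomal glycoprotein GPNMB (2.22 ± 0.12) and cathepsin D, CTSD (1.10 ± 0.083). Of 16 antigen presentation genes, 13 rose and 3 did not pass (median 0.63, adjusted p = 2.12e-05). The class II genes HLA-DMA and CD74 had 1.44 ± 0.13 and 1.32 ± 0.12. Of 33 interferon response genes, 23 rose, 2 fell and 8 did not pass (median 0.50, adjusted p = 7.89e-06; adjusted p = 0.0523 with an estimated correlation). IFI27 had 1.90 ± 0.078 and RSAD2 1.43 ± 0.11. TGF-beta and SMAD targets moved up as well: of 19, 13 rose, 1 fell and 5 did not pass (over the list alone, 14 rose and 1 fell; median 0.65, adjusted p = 9.62e-06; adjusted p = 0.0526 with an estimated correlation). Among them the inhibitors of DNA binding ID1, ID2 and ID3 rose by 1.80 ± 0.076, 1.78 ± 0.079 and 1.64 ± 0.079 and the receptor decoy BAMBI by 2.04 ± 0.077. Of 20 actin and SRF targets, 11 rose and 9 did not pass (over the list alone, 12 rose and 1 fell; median 0.33, adjusted p = 0.00573). TAGLN had 2.18 ± 0.12 and CALD1 0.93 ± 0.10; this list's call ended with median centring (median 0.16, adjusted p = 0.053).

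Over all genes 6478 (49.2%) passed limma's test with MEK inhibition, 3421 higher and 3057 lower, and 777 of them changed at least 2-fold, 542 up and 235 down. With each array centred on its median in place of quantile normalization, 2754 genes were higher and 3814 lower, and ribosomal proteins (median -0.20), oxidative phosphorylation (-0.32) and cytosolic heat shock (-0.56) came to pass; without the filter on dim probes, heat shock (-0.36) and cholesterol synthesis (0.17) did. SRC had 0.40 ± 0.081 (adjusted p = 0.00127) on the probe fitted, its probes differed in sign (-0.15 and 0.40), and the mean of its probes gave 0.12 (adjusted p = 0.4). The death-promoting BCL2 relative BCL2L11 had -0.25 ± 0.11 (adjusted p = 0.0933) on the probe fitted and 0.14 on its other probe, and passed without control replicate 3 (-0.33) and with the replicate number as a block (adjusted p = 0.0416). The insulin receptor INSR (0.28 ± 0.14) passed only without MEK inhibition replicate 3 (0.39). The RAS regulator NF1 (0.078 ± 0.17) and the aldehyde dehydrogenase ALDH1A1 (-0.011 ± 0.10) did not pass. INSR and ALDH1A1 were detected on 1 array of their dim group, so neither shows a lack of change.

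**Figure D2:**
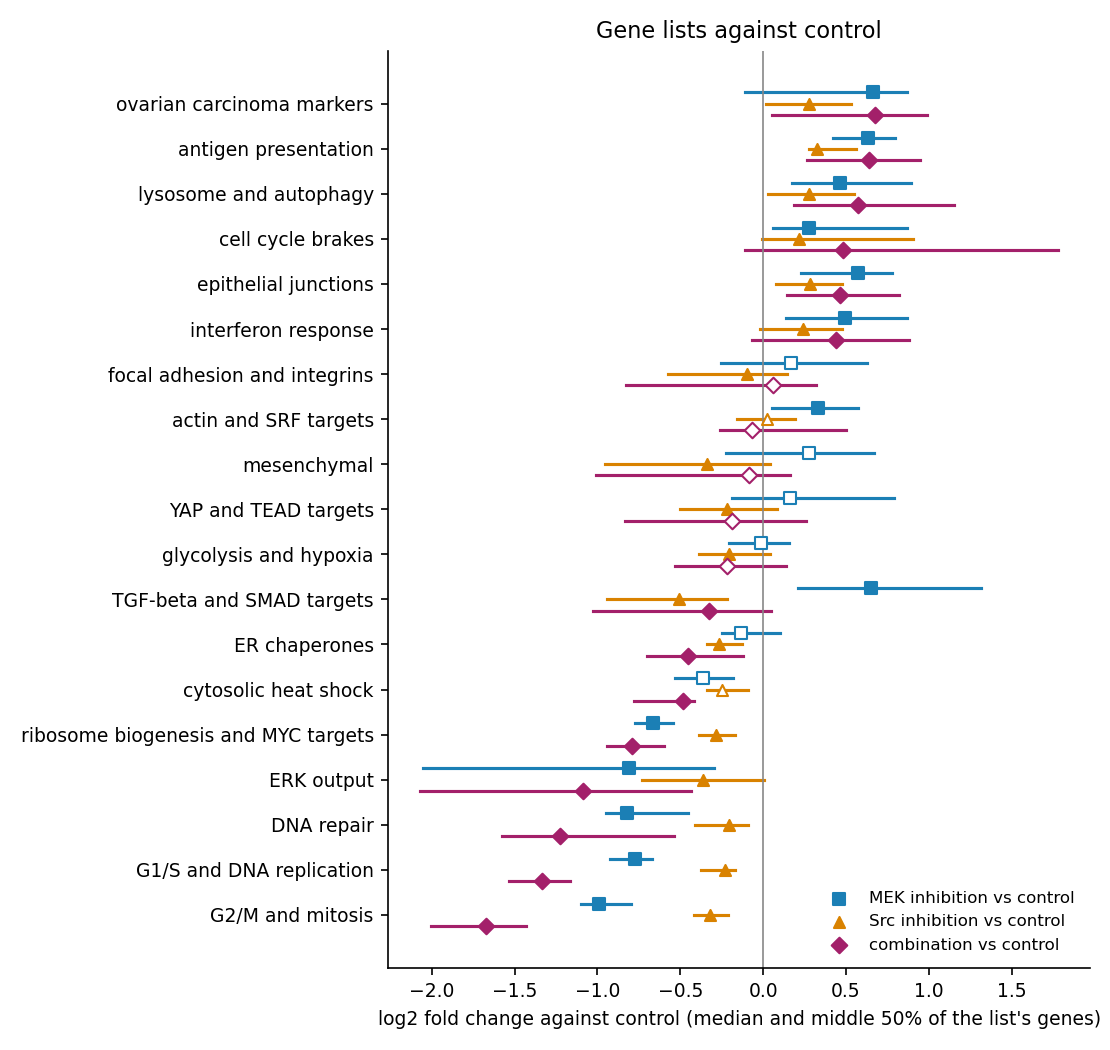
Median log2 fold change against control (horizontal) of the measured genes of each of 19 lists (vertical), for MEK inhibition, Src inhibition and the combination; bars span the middle 50% of the genes, and filled markers passed camera's test at an adjusted p under 0.05. The G2/M and mitosis list lies at -0.99, -0.32 and -1.67, and TGF-beta and SMAD targets at 0.65, -0.51 and -0.33.

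Src inhibition was compared with control to ask which transcripts changed when Src alone was inhibited. VTCN1 rose here too, 13.9-fold (log2 change 3.79 ± 0.10, adjusted p = 6.22e-10), as did the cytochrome CYP1A2, 6.65-fold (2.73 ± 0.080), and the lipid transporter ABCA4, 5.51-fold (2.46 ± 0.10). The epidermal protein FLG (filaggrin) rose 5.41-fold (2.43 ± 0.16) and the epithelial keratin KRT15 5.39-fold (2.43 ± 0.079). ESM1 fell 7.12-fold (log2 change -2.83 ± 0.078, adjusted p = 6.22e-10), the mesenchymal cadherin CDH11 fell 5.64-fold (-2.50 ± 0.14) and MARCHF4 fell 4.47-fold (-2.16 ± 0.13). KANK4, a member of a family of actin regulators, fell at least 3.82-fold, ID1 fell 3.41-fold (-1.77 ± 0.076) and the integrin subunit ITGB6 fell at least 2.91-fold. Of 25 ERK output genes, 4 rose, 13 fell and 8 did not pass (median -0.36, adjusted p = 0.00192): ETV4 changed by -0.89 ± 0.13, ETV5 by -0.76 ± 0.12, FOSL1 by -0.73 ± 0.15, SPRY4 by -0.59 ± 0.10 and the chromatin protein HMGA2 by -1.22 ± 0.12, while the neutrophil-attracting chemokine CXCL8 rose (0.95 ± 0.085). MYC fell (-0.38 ± 0.090; -0.17 on its other probe). DUSP6 had -0.36 ± 0.17 (adjusted p = 0.139) with all arrays and passed without Src inhibition replicate 3 (-0.59, adjusted p = 0.00758).

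TGF-beta and SMAD targets and mesenchymal genes were lower as lists with Src inhibition. Of 19 TGF-beta and SMAD targets, 2 rose, 13 fell and 4 did not pass (over the list alone, 2 rose and 14 fell; median -0.51, adjusted p = 4.11e-07). ID2 had -1.18 ± 0.079, the TGF-beta feedback gene PMEPA1 -1.26 ± 0.078 and the basement membrane collagen COL4A1 -0.95 ± 0.073. Of 16 mesenchymal genes, 1 rose, 9 fell and 6 did not pass (over the list alone, 2 rose and 9 fell; median -0.34, adjusted p = 0.000823), such as fibronectin, FN1 (-1.49 ± 0.15), the transcription factor SNAI2 (at least 2.63-fold) and the collagen-crosslinking enzyme LOX (-1.02 ± 0.10). Of 22 YAP and TEAD targets, 4 rose, 10 fell and 8 did not pass (over the list alone, 5 rose and 11 fell; median -0.22, adjusted p = 0.0071; adjusted p = 0.0852 with an estimated correlation). IGFBP3 had -1.62 ± 0.10 and the receptor kinase AXL -0.93 ± 0.14. Of 23 focal adhesion and integrin genes, 3 rose, 8 fell and 12 did not pass (median -0.10, adjusted p = 0.0198; adjusted p = 0.0576 with an estimated correlation). ITGA6 had -1.20 ± 0.12 and CAV2 -0.62 ± 0.072; the median was -0.20 without Src inhibition replicate 3. Of 16 ER chaperones, 8 fell and 8 did not pass (over the list alone, 9 fell; median -0.27, adjusted p = 0.000816; adjusted p = 0.0724 with an estimated correlation). HYOU1 had -0.47 ± 0.12 and PDIA6 -0.43 ± 0.10. Of 30 genes of glycolysis and hypoxia, 4 rose, 12 fell and 14 did not pass (over the list alone, 4 rose and 16 fell; median -0.20, adjusted p = 0.0138; adjusted p = 0.127 with an estimated correlation). PGAM1 had -0.48 ± 0.072 and, upward, the carbonic anhydrase CA12 1.41 ± 0.14.

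The cell division lists fell with Src inhibition too. Of 34 genes of G2/M and mitosis, 20 fell and 14 did not pass (over the list alone, 24 fell; median -0.32, adjusted p = 1.87e-08). CENPE had -0.59 ± 0.068 and CCNA2 -0.56 ± 0.065. Of 36 genes of G1/S and DNA replication, 13 fell and 23 did not pass (over the list alone, 21 fell; median -0.23, adjusted p = 1.82e-07). UHRF1 had -0.73 ± 0.076. Of 31 ribosome biogenesis genes and MYC targets, 15 fell and 16 did not pass (over the list alone, 18 fell; median -0.28, adjusted p = 1.45e-06). Of 21 DNA repair genes, 8 fell and 13 did not pass (median -0.21, adjusted p = 0.000584). Upward, of 24 epithelial junction genes, 12 rose and 12 did not pass (median 0.28, adjusted p = 0.000134). The claudin CLDN3 had 0.99 ± 0.10 and ELF3 0.74 ± 0.10. Of 16 antigen presentation genes, 10 rose and 6 did not pass (over the list alone, 14 rose; median 0.33, adjusted p = 3.6e-05). CD74 had 1.10 ± 0.12. Of 33 interferon response genes, 15 rose, 3 fell and 15 did not pass (over the list alone, 19 rose and 3 fell; median 0.24, adjusted p = 0.000823; adjusted p = 0.108 with an estimated correlation). IFI27 had 1.18 ± 0.078. Of 28 lysosome and autophagy genes, 15 rose, 1 fell and 12 did not pass (over the list alone, 17 rose and 1 fell; median 0.28, adjusted p = 3.6e-05). GPNMB had 1.79 ± 0.12 and CTSD 0.93 ± 0.083. Of 22 cell cycle brakes, 10 rose and 12 did not pass (median 0.22, adjusted p = 0.000823). CITED2 had 1.28 ± 0.081 and TXNIP 1.24 ± 0.10. Of 18 ovarian carcinoma markers, 9 rose, 2 fell and 7 did not pass (median 0.28, adjusted p = 0.00545). MUC16 had 2.42 ± 0.13 and the secreted protein WFDC2 1.29 ± 0.091.

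Over all genes 3796 (28.8%) passed limma's test with Src inhibition, 2115 higher and 1681 lower, and 224 of them changed at least 2-fold, 166 up and 58 down. With only these 2 groups fitted 2858 passed, and 4006 without Src inhibition replicate 3 (2273 higher, 1733 lower). Median centring gave 1779 higher and 2277 lower. Without Src inhibition replicate 3, 3 more lists passed: NF-kB and inflammatory cytokines (median 0.19), cytosolic heat shock (-0.21) and the ATF4 and amino acid response (0.22), the last also without control replicate 3 (0.12). Each also passed in 3 alternatives with all arrays, at 0.048 to 0.097, -0.35 to -0.20 and 0.11, and ribosomal proteins passed with median centring (-0.14). EGR1 had 0.27 ± 0.089 (adjusted p = 0.0372), a call that 10 of 23 alternatives ended, at 0.22 to 0.30, among them leaving out control replicate 2 or 3, MEK inhibition replicate 1 or 2, or any of the 3 Src inhibition arrays. CDKN1B had 0.39 ± 0.11 (adjusted p = 0.0226), a call that ended in 5 alternatives, at 0.28 to 0.39, among them leaving out control replicate 2 or 3 or Src inhibition replicate 3; its other probe had 0.095. CCND1 (-0.12 ± 0.068) passed with median centring alone (-0.21, adjusted p = 0.0454), and MAP2K1 (-0.19 ± 0.076) passed in 3 alternatives with no array left out, at -0.27 to -0.17. INSR (0.33 ± 0.14) passed without combination replicate 3 (0.33), whereas CDKN1A (-0.13 ± 0.12), BCL2L11 (0.040 ± 0.11), SRC (0.0070 ± 0.081), NF1 (0.019 ± 0.17) and ALDH1A1 (0.018 ± 0.10) did not pass, and the probes of BCL2L11 and SRC differed in sign.

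The combination was compared with control to ask which transcripts changed when MEK and Src were inhibited together. VTCN1 rose 35.9-fold (log2 change 5.17 ± 0.10, adjusted p = 9.83e-12), the mucin MUC1 22.7-fold (4.50 ± 0.12) and the proton pump subunit ATP6V1B1 21.7-fold (4.44 ± 0.11). ABCA4 rose 18.1-fold (4.18 ± 0.10), the vesicle-docking protein SYTL2 15-fold (3.91 ± 0.10) and MUC16, a mucin of ovarian cancer, 14-fold (3.81 ± 0.13). ESM1 fell 19.5-fold (log2 change -4.29 ± 0.078, adjusted p = 7.72e-12), CDH11 12-fold (-3.59 ± 0.14), MARCHF4 at least 10.2-fold, HAS3 10.6-fold (-3.40 ± 0.084) and the lipase LIPG 8.71-fold (-3.12 ± 0.12). DUSP4 was at least 6.03-fold lower than in control, a bound used because its probe was detected on none of the 3 combination arrays. Of 25 ERK output genes, 3 rose, 20 fell and 2 did not pass (over the list alone, 3 rose and 21 fell; median -1.09, adjusted p = 2.92e-07). DUSP6 had -2.16 ± 0.17, ETV4 -2.72 ± 0.13, ETV5 -2.67 ± 0.12, FOSL1 -2.52 ± 0.15 and PHLDA1 -2.07 ± 0.082. SPRY4 was at least 3.46-fold lower, a bound for the same reason. Other probes gave smaller changes for MUC1 (0.945), SYTL2 (1.07), PHLDA1 (-0.59), DUSP6 (-0.925), ETV5 (-1.425), ID2 (-0.41) and CDKN1B (0.447). EGR1 (-1.24 ± 0.089), MYC (-0.43 ± 0.090), CCND1 (-0.74 ± 0.068) and MAP2K1 (-0.44 ± 0.076) fell.

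**Figure D3:**
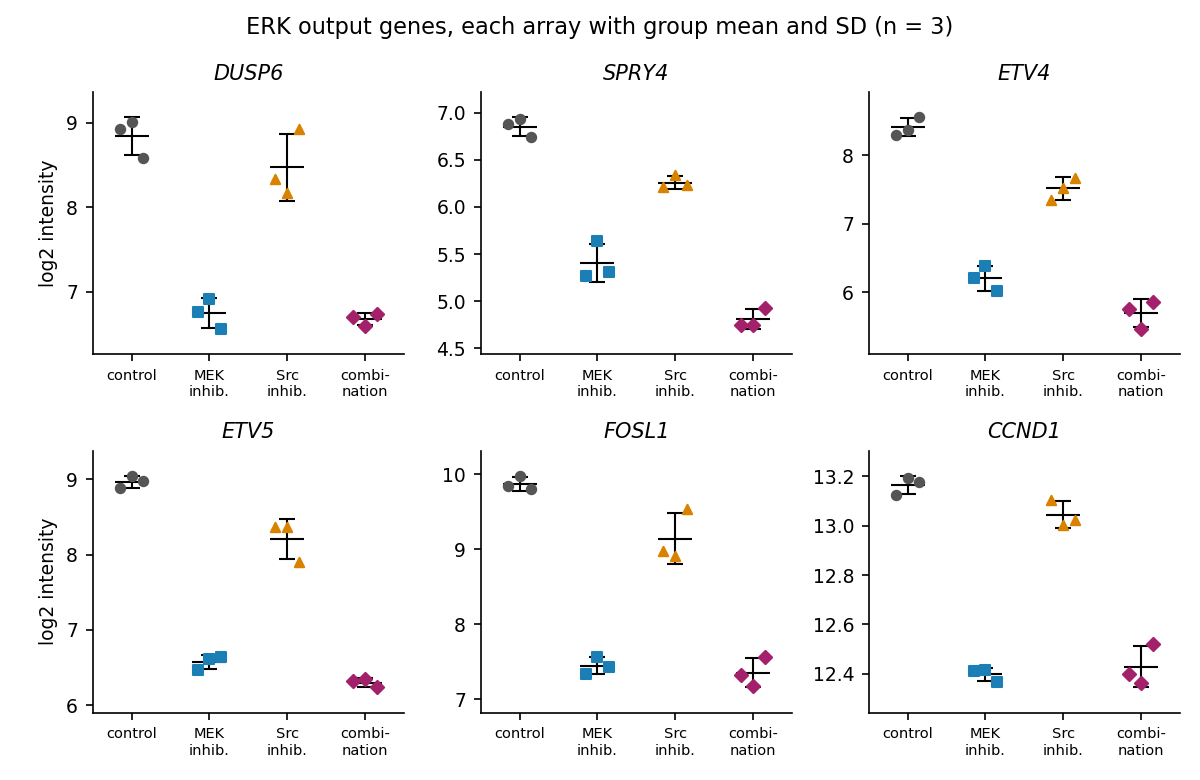
Log2 level (vertical) of DUSP6, SPRY4, ETV4, ETV5, FOSL1 and CCND1 on each of the 12 arrays (points) by group (horizontal), with the group mean and SD of 3 arrays in black. DUSP6 lies at 8.84 ± 0.22 in control (mean ± SD), 6.74 ± 0.18 with MEK inhibition, 8.47 ± 0.40 with Src inhibition and 6.68 ± 0.073 in the combination.

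Cell division genes were far lower in the combination than in control. Of 34 genes of G2/M and mitosis, 33 fell and 1 did not pass (median -1.67, adjusted p = 5.73e-20). CCNA2 had -2.23 ± 0.065, the topoisomerase TOP2A -2.06 ± 0.065 and BUB1 -2.01 ± 0.070. Of 36 genes of G1/S and DNA replication, 35 fell and 1 did not pass (median -1.33, adjusted p = 1.67e-17). UHRF1 had -2.05 ± 0.076, CDC45 -1.96 ± 0.073 and the ribonucleotide reductase subunit RRM2 -1.94 ± 0.088. Of 21 DNA repair genes, 1 rose and 20 fell (median -1.22, adjusted p = 1.02e-08). EXO1 had -1.94 ± 0.085 and RAD51AP1 -1.75 ± 0.089. Of 31 genes of ribosome biogenesis and MYC targets, 29 fell and 2 did not pass (median -0.79, adjusted p = 5.84e-10). NOLC1 had -1.43 ± 0.063. Of 22 cell cycle brakes, 12 rose, 5 fell and 5 did not pass (over the list alone, 13 rose and 5 fell; median 0.48, adjusted p = 0.0114; adjusted p = 0.0956 with an estimated correlation). TXNIP had 2.44 ± 0.10, KLHL24 2.28 ± 0.092 and CITED2 2.25 ± 0.081. CDKN1B rose (0.85 ± 0.11) and CDKN1A fell (-0.80 ± 0.12). Of 14 cytosolic heat shock genes, 2 rose, 11 fell and 1 did not pass (median -0.48, adjusted p = 0.0131; adjusted p = 0.0614 with an estimated correlation): HSPA4L had -1.47 ± 0.10, while the small chaperones CRYAB and HSPB1 rose (3.0 ± 0.071 and 1.01 ± 0.068). Of 16 ER chaperones, 11 fell and 5 did not pass (median -0.45, adjusted p = 0.00708; adjusted p = 0.169 with an estimated correlation). PDIA6 had -0.85 ± 0.10.

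Ovarian carcinoma markers and lysosomal genes were higher in the combination. Of 18 ovarian carcinoma markers, 12 rose, 3 fell and 3 did not pass (median 0.67, adjusted p = 0.00677). MSLN had 1.79 ± 0.070, CLDN3 1.70 ± 0.10 and WFDC2 1.51 ± 0.091. Of 28 genes of lysosome and autophagy, 21 rose, 1 fell and 6 did not pass (median 0.57, adjusted p = 9.1e-06). GPNMB had 2.60 ± 0.12, CTSD 1.39 ± 0.083 and the sialidase NEU1 1.04 ± 0.069. Of 24 epithelial junction genes, 16 rose, 1 fell and 7 did not pass (median 0.47, adjusted p = 0.0023). ELF3 had 1.64 ± 0.10. Of 16 antigen presentation genes, 12 rose, 1 fell and 3 did not pass (median 0.64, adjusted p = 0.00124; adjusted p = 0.0614 with an estimated correlation). CD74 had 2.01 ± 0.12 and HLA-DMA 1.64 ± 0.13. Of 33 interferon response genes, 20 rose, 7 fell and 6 did not pass (median 0.44, adjusted p = 0.0163; adjusted p = 0.314 with an estimated correlation). IFI27 had 2.03 ± 0.078 and the interferon factor IRF9 1.69 ± 0.10. Of 19 TGF-beta and SMAD targets, 2 rose, 10 fell and 7 did not pass (median -0.33, adjusted p = 0.0163; adjusted p = 0.314 with an estimated correlation). ID1 had -1.36 ± 0.076, ID2 -1.14 ± 0.079 and the matrix protein LTBP2 -1.80 ± 0.13.

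Over all genes 8008 (60.8%) passed in the combination, 4212 higher and 3796 lower (3869 and 4153 with median centring), and 1636 of them changed at least 2-fold, 913 up and 723 down. In all 3 comparisons with control 3029 genes passed in 1 direction, and 1935 passed in the combination and in neither single treatment, 21 of these by at least 2-fold and 128 with an interaction that passed. With median centring oxidative phosphorylation passed as a list (-0.24). BCL2L11 had -0.37 ± 0.11 (adjusted p = 0.0134), a call that ended with the mean of its probes (-0.17), in the authors' value table (-0.097) and without control replicate 2 (-0.31) or combination replicate 3 (-0.32). SRC had 0.26 ± 0.081 (adjusted p = 0.0141), a call that ended with the mean of its probes (0.027) and with median centring (0.16). The probes of BCL2L11, of SRC and of CALB2 (-1.37 and 0.10) differed in sign. ALDH1A1 (-0.18 ± 0.10), which passed without control replicate 2 (-0.29), INSR (-0.082 ± 0.14) and NF1 (-0.15 ± 0.17) did not pass.

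The other lists did not pass camera's test in any comparison with control with the settings used for the counts, and each is given as the number of genes that rose and the number that fell, under MEK inhibition, Src inhibition and the combination in turn. The 21 ribosomal protein genes counted 1 and 2, 1 and 1, and 2 and 4 (over the list alone, 1 and 1, 0 and 0, and 2 and 3; adjusted p = 0.267, 0.376 and 0.732). The 28 genes of oxidative phosphorylation counted 2 and 7, 0 and 1, and 3 and 9 (over the list alone, 2 and 6, 0 and 0, and 3 and 7; adjusted p = 0.208, 0.985 and 0.264). The 19 cholesterol synthesis genes counted 8 and 1, 3 and 2, and 6 and 5 (adjusted p = 0.0906, 0.492 and 0.661), with the sterol reductase TM7SF2 at 1.97 ± 0.078, 1.07 ± 0.078 and 2.0 ± 0.078. The 14 fatty acid synthesis genes counted 4 and 3, 3 and 2, and 3 and 8 (over the list alone, 4 and 3, 3 and 3, and 3 and 8; adjusted p = 0.798, 0.752 and 0.383), with the fatty acid-binding protein FABP5 at -1.18 ± 0.080, -0.77 ± 0.080 and -1.91 ± 0.080, and the lipogenic THRSP at least 2.29-fold, 1.65-fold and 6.76-fold higher, its probe being detected on no control array. The 13 NRF2 targets counted 3 and 5, 4 and 0, and 5 and 3 (adjusted p = 0.798, 0.14 and 0.519), with the drug efflux pump ABCC3 at 0.98 ± 0.10, 1.05 ± 0.10 and 1.53 ± 0.10. The 26 genes of ATF4 and the amino acid response counted 11 and 6, 9 and 1, and 12 and 6 (over the list alone, 11 and 7, 11 and 3, and 12 and 6; adjusted p = 0.294, 0.0624 and 0.316), with NUPR1 at 1.21 ± 0.12, 1.21 ± 0.12 and 2.20 ± 0.12. The 20 p53 targets counted 5 and 9, 5 and 3, and 7 and 9 (over the list alone, 6 and 9, 5 and 3, and 7 and 10; adjusted p = 0.421, 0.796 and 0.657).

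The 18 immediate early genes counted 6 and 5, 7 and 3, and 8 and 8 (over the list alone, 6 and 5, 7 and 4, and 8 and 9; adjusted p = 0.755, 0.624 and 0.852), with KLF6 at 0.90 ± 0.079, 0.58 ± 0.079 and 0.95 ± 0.079. The 23 receptor kinases and adaptors counted 6 and 5, 5 and 6, and 7 and 8 (over the list alone, 6 and 5, 7 and 7, and 8 and 8; adjusted p = 0.798, 0.791 and 0.671), with the docking protein GAB2 at 1.20 ± 0.081, 1.10 ± 0.081 and 1.89 ± 0.081. The 23 genes of the Src family and MAPK cascade counted 3 and 4, 2 and 1, and 6 and 6 (over the list alone, 3 and 4, 1 and 1, and 5 and 6; adjusted p = 0.798, 0.207 and 0.845), with HRAS at -0.67 ± 0.072, -0.31 ± 0.072 and -0.84 ± 0.072. The 11 WNT targets counted 4 and 2, 3 and 0, and 4 and 2 (over the list alone, 4 and 2, 3 and 0, and 6 and 2; adjusted p = 0.367, 0.321 and 0.473), with SOX4 at 1.91 ± 0.072, 0.65 ± 0.072 and 1.27 ± 0.072. The 21 genes of NF-kB and inflammatory cytokines counted 12 and 4, 6 and 2, and 5 and 7 (over the list alone, 12 and 5, 8 and 2, and 5 and 7; adjusted p = 0.208, 0.0624 and 0.732). The 9 survival genes counted 3 and 2, 1 and 1, and 3 and 2 (adjusted p = 0.798, 0.276 and 0.661), with the caspase inhibitor CFLAR at 0.83 ± 0.070, 0.37 ± 0.070 and 1.13 ± 0.070. The 11 death-promoting BCL2 family genes counted 3 and 1, 1 and 0, and 6 and 3 (over the list alone, 2 and 1, 1 and 0, and 6 and 3; adjusted p = 0.337, 0.607 and 0.424), with BMF at 2.31 ± 0.10 under MEK inhibition and 1.33 ± 0.10 in the combination. The 16 markers of ovarian stem-like cells counted 6 and 4, 5 and 3, and 7 and 4 (over the list alone, 6 and 4, 6 and 3, and 7 and 4; adjusted p = 0.507, 0.132 and 0.332).

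The 12 housekeeping genes counted 2 and 3, 2 and 1, and 1 and 7 (over the list alone, 2 and 3, 2 and 3, and 1 and 7; adjusted p = 0.798, 0.607 and 0.213). The 6 measured melanocyte markers counted 2 and 0, 1 and 0, and 2 and 1 (adjusted p = 0.798, 0.791 and 0.806). Too few markers were measured to test as lists for 3 other cell types: 4 fibroblast markers counted 1 and 0, 1 and 1, and 1 and 1, with THY1 at 1.03 ± 0.071, 0.76 ± 0.071 and 1.40 ± 0.071. The 3 leukocyte markers counted 0 and 0, 1 and 0, and 2 and 0. The 3 endothelial markers counted 1 and 0, 1 and 0, and 1 and 0, with CDH5 at least 1.99-fold higher with MEK inhibition and 1.20-fold higher in the combination, its probe being detected on no control array. Median, mean and test differed in sign for survival genes (median 0.12, mean -0.0082), for the Src family and MAPK cascade (0.034, -0.011), for glycolysis and hypoxia (-0.015, 0.15) and, in the test alone, for NRF2 targets (0.020, 0.026) under MEK inhibition. They differed for fatty acid synthesis (-0.066, 0.036) and melanocyte markers (-0.020, 0.058) under Src inhibition, and for actin and SRF targets (-0.068, 0.11) and focal adhesion and integrins (0.058, -0.19) in the combination.

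The combination was compared with MEK inhibition to ask what Src inhibition added to MEK inhibition. KANK4 fell 11.5-fold (log2 change -3.52 ± 0.12, adjusted p = 4.32e-09), ID1 fell 8.95-fold (-3.16 ± 0.076), the vitamin D-degrading enzyme CYP24A1 8.04-fold (-3.01 ± 0.11) and ID2 7.57-fold (-2.92 ± 0.079). The proton pump subunit ATP6V1B1 rose 6.44-fold (log2 change 2.69 ± 0.11, adjusted p = 1.81e-08), the mucin-type glycosyltransferase GCNT3 at least 4.83-fold, FLG 4.74-fold (2.25 ± 0.16) and angiotensinogen, AGT, 4.65-fold (2.22 ± 0.092). Of 19 TGF-beta and SMAD targets, 15 fell and 4 did not pass (median -0.96, adjusted p = 1.15e-15). COL4A1 had -1.93 ± 0.073 and the circadian repressor BHLHE40 -1.53 ± 0.072. Of 16 mesenchymal genes, 1 rose, 9 fell and 6 did not pass (over the list alone, 1 rose and 10 fell; median -0.51, adjusted p = 0.000121). FN1 had -2.69 ± 0.15 and N-cadherin (CDH2) -1.80 ± 0.078. ITGB6, detected on no combination array, was at least 4.97-fold lower. Of 34 genes of G2/M and mitosis, 1 rose, 32 fell and 1 did not pass (over the list alone, 1 rose and 33 fell; median -0.72, adjusted p = 6.89e-21). KIF4A had -1.12 ± 0.075 and TOP2A -0.99 ± 0.065. Of 36 genes of G1/S and DNA replication, 30 fell and 6 did not pass (over the list alone, 31 fell; median -0.54, adjusted p = 2.28e-15). RRM2 had -1.31 ± 0.088. Of 21 DNA repair genes, 1 rose, 15 fell and 5 did not pass (over the list alone, 1 rose and 16 fell; median -0.37, adjusted p = 1.28e-06).

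**Figure D4:**
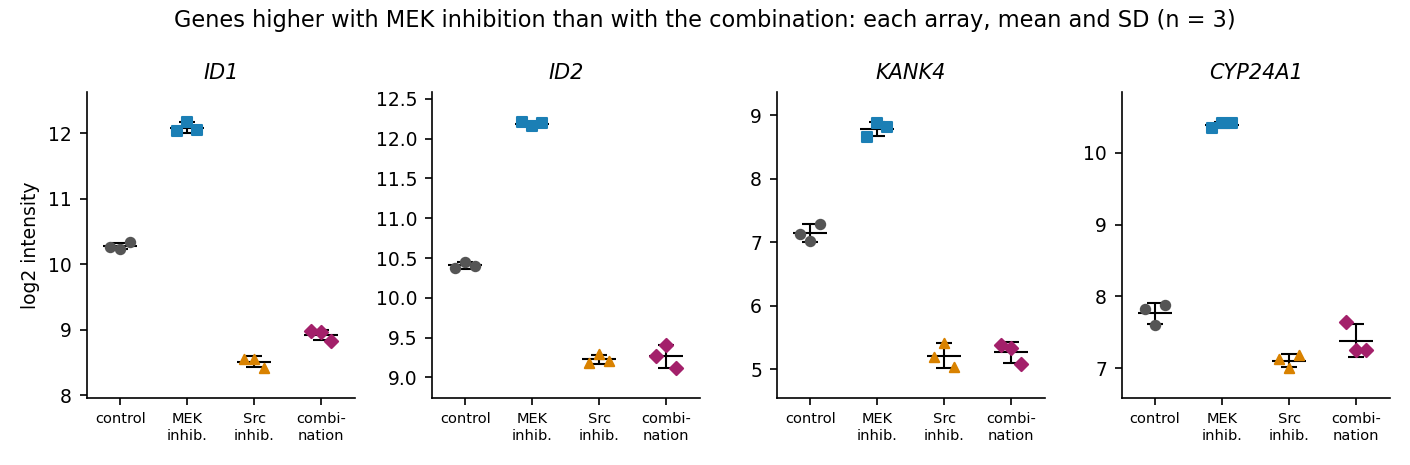
Log2 level (vertical) of ID1, ID2, KANK4 and CYP24A1 on each of the 12 arrays (points) by group (horizontal), with the group mean and SD of 3 arrays in black. ID1 lies at 10.28 ± 0.049 in control (mean ± SD), 12.08 ± 0.079 with MEK inhibition, 8.51 ± 0.084 with Src inhibition and 8.92 ± 0.078 in the combination.

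Against MEK inhibition, ERK output did not move as a list: of 25 genes, 3 rose, 8 fell and 14 did not pass (median -0.093, adjusted p = 0.0987). DUSP6 (-0.066 ± 0.17), FOSL1 (-0.093 ± 0.15) and ETV5 (-0.27 ± 0.12) did not pass, although ETV5 passed without Src inhibition replicate 3 (-0.27, adjusted p = 0.00913). SPRY4 was at least 1.27-fold lower, and ETV4 had -0.51 ± 0.13 (adjusted p = 0.00972), a call that ended in the authors' value table (-0.14). EGR1 fell (-0.51 ± 0.089), CDKN1A fell (-0.96 ± 0.12) and CDKN1B rose (0.48 ± 0.11). CCND1 (0.030 ± 0.068), MYC (-0.031 ± 0.090), MAP2K1 (-0.10 ± 0.076), SRC (-0.14 ± 0.081), BCL2L11 (-0.12 ± 0.11), NF1 (-0.23 ± 0.17) and ALDH1A1 (-0.17 ± 0.10) did not pass, nor did INSR (-0.36 ± 0.14), which passed without MEK inhibition replicate 3 (-0.47) or combination replicate 1 (-0.50), or with the replicate block (-0.36).

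Another 10 lists passed camera's test against MEK inhibition with the preset correlation only. Of 16 ER chaperones, 11 fell and 5 did not pass (median -0.33, adjusted p = 0.000353; adjusted p = 0.0723 with an estimated correlation). PDIA6 had -0.61 ± 0.10. Of 22 YAP and TEAD targets, 2 rose, 11 fell and 9 did not pass (median -0.28, adjusted p = 0.000993; adjusted p = 0.0663 with an estimated correlation). The matricellular genes CCN1 and CCN2 had -1.06 ± 0.082 and -1.05 ± 0.11. Of 20 actin and SRF targets, 1 rose, 6 fell and 13 did not pass (median -0.20, adjusted p = 0.00695; adjusted p = 0.0518 with an estimated correlation). Thrombospondin (THBS1) had -2.30 ± 0.10. Of 21 genes of NF-kB and inflammatory cytokines, 7 fell and 14 did not pass (over the list alone, 1 rose and 9 fell; median -0.21, adjusted p = 0.012; adjusted p = 0.0724 with an estimated correlation). CCL2 had -1.65 ± 0.090. Of 30 genes of glycolysis and hypoxia, 2 rose, 11 fell and 17 did not pass (median -0.15, adjusted p = 0.0107; adjusted p = 0.0975 with an estimated correlation). PGAM1 had -1.02 ± 0.072. Of 14 heat shock genes, 1 rose, 5 fell and 8 did not pass (over the list alone, 1 rose and 7 fell; median -0.18, adjusted p = 0.012; adjusted p = 0.0663 with an estimated correlation). Upward, of 22 cell cycle brakes, 10 rose, 3 fell and 9 did not pass (over the list alone, 11 rose and 3 fell; median 0.24, adjusted p = 0.0116; adjusted p = 0.078 with an estimated correlation). TXNIP had 1.02 ± 0.10. Of 28 lysosome and autophagy genes, 11 rose and 17 did not pass (over the list alone, 13 rose and 1 fell; median 0.16, adjusted p = 0.0135; adjusted p = 0.0975 with an estimated correlation). Of 13 NRF2 targets, 8 rose and 5 did not pass (median 0.26, adjusted p = 0.012; adjusted p = 0.0663 with an estimated correlation). Heme oxygenase (HMOX1) had 0.89 ± 0.15. Of 31 genes of ribosome biogenesis and MYC targets, 5 fell and 26 did not pass (median -0.11, adjusted p = 0.0427; adjusted p = 0.078 with an estimated correlation), and this call ended without MEK inhibition replicate 1 (-0.097) or 2 (-0.12) or combination replicate 1 (-0.092) or 2 (-0.073). In alternatives with all arrays, focal adhesion and integrins (-0.13 and -0.069), ovarian carcinoma markers (0.028 to 0.086) and cholesterol synthesis (-0.10) passed in 2, 3 and 1. Over all genes 3898 (29.6%) passed, 1947 higher and 1951 lower (2115 and 1622 with median centring), 86 and 118 of them by at least 2-fold.

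The combination was compared with Src inhibition to ask what MEK inhibition added to Src inhibition. MUC1 rose 5.48-fold (log2 change 2.45 ± 0.12, adjusted p = 5.47e-08), ATP6V1B1 4.91-fold (2.29 ± 0.11), GCNT3 4.32-fold (2.11 ± 0.11) and the small nucleolar RNA SNORD3C 4.20-fold (2.07 ± 0.15). LIPG fell 4.64-fold (log2 change -2.21 ± 0.12, adjusted p = 8.71e-08), HAS3 4.34-fold (-2.12 ± 0.084) and CXCL8 4.20-fold (-2.07 ± 0.085), and DUSP4 was at least 3.1-fold lower. Of 25 ERK output genes, 1 rose, 18 fell and 6 did not pass (median -0.62, adjusted p = 7.4e-09). DUSP6 had -1.80 ± 0.17, ETV4 -1.82 ± 0.13, ETV5 -1.91 ± 0.12, FOSL1 -1.79 ± 0.15 and EGR1 -1.51 ± 0.089, and SPRY4 was at least 2.29-fold lower. All 34 genes of G2/M and mitosis fell (median -1.38, adjusted p = 1.18e-28). KIF4A had -1.73 ± 0.075 and CCNA2 -1.67 ± 0.065. Of 36 genes of G1/S and DNA replication, 34 fell and 2 did not pass (over the list alone, 35 fell; median -1.08, adjusted p = 1.67e-23). Of 21 DNA repair genes, 18 fell and 3 did not pass (median -0.94, adjusted p = 7.8e-11). RAD51AP1 had -1.45 ± 0.089. Of 31 genes of ribosome biogenesis and MYC targets, 26 fell and 5 did not pass (median -0.53, adjusted p = 3.27e-10). NOLC1 had -1.0 ± 0.063. Upward, of 28 lysosome and autophagy genes, 18 rose, 1 fell and 9 did not pass (over the list alone, 19 rose and 1 fell; median 0.41, adjusted p = 2.92e-05). The autophagy genes GABARAPL1 and ULK1 had 1.26 ± 0.14 and 1.02 ± 0.11. Of 18 ovarian carcinoma markers, 12 rose, 1 fell and 5 did not pass (over the list alone, 13 rose and 1 fell; median 0.34, adjusted p = 0.0042). MUC16 had 1.40 ± 0.13. TGF-beta and SMAD targets did not pass as a list: of 19, 6 rose, 3 fell and 10 did not pass (median 0.037, adjusted p = 0.704).

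With MEK inhibition added, 4 lists passed with the preset correlation only. Of 22 cell cycle brakes, 12 rose, 4 fell and 6 did not pass (over the list alone, 12 rose and 5 fell; median 0.31, adjusted p = 0.0284; adjusted p = 0.137 with an estimated correlation). Of 24 epithelial junction genes, 14 rose, 2 fell and 8 did not pass (median 0.26, adjusted p = 0.0465; adjusted p = 0.118 with an estimated correlation). Of 16 antigen presentation genes, 8 rose and 8 did not pass (over the list alone, 9 rose; median 0.25, adjusted p = 0.0465; adjusted p = 0.231 with an estimated correlation). Of 14 heat shock genes, 2 rose, 8 fell and 4 did not pass (median -0.29, adjusted p = 0.0465; adjusted p = 0.12 with an estimated correlation). The calls of these last 3 lists also ended, in 1 or more of them, without each of the 12 arrays but MEK inhibition replicate 3, with medians of 0.19 to 0.27, 0.21 to 0.25 and -0.32 to -0.23, and the first 2 with median centring (0.21 and 0.23). CCND1 (-0.61 ± 0.068) and CDKN1A (-0.67 ± 0.12) fell and CDKN1B rose (0.46 ± 0.11). SRC had 0.25 ± 0.081 (adjusted p = 0.0235), a call that ended in 6 alternatives, at 0.098 to 0.25, among them leaving out Src inhibition replicate 1 or 2 or combination replicate 3. INSR, detected on 1 of 3 combination arrays, had -0.41 ± 0.14 (adjusted p = 0.0326), which 7 alternatives ended, at -0.43 to -0.098, among them leaving out Src inhibition replicate 1 or 2 or combination replicate 2 or 3 (-0.25 without the last). MAP2K1 had -0.25 ± 0.076 (adjusted p = 0.0166), a call that ended without Src inhibition replicate 1 (-0.21) or combination replicate 3 (-0.22), and BCL2L11 had -0.41 ± 0.11, a call that ended with the mean of its probes (-0.13). MYC (-0.056 ± 0.090), NF1 (-0.17 ± 0.17) and ALDH1A1 (-0.20 ± 0.10) did not pass. Oxidative phosphorylation passed in 3 alternatives with all arrays (-0.14 to -0.13) and interferon response in 1 (0.20). Over all genes 5777 (43.9%) passed, 3061 higher and 2716 lower, 182 and 286 of them by at least 2-fold.

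MEK inhibition was compared with Src inhibition to test directly where the single treatments differed. KANK4 was at least 11.9-fold higher with MEK inhibition (adjusted p = 2.68e-09), ID1 11.9-fold (3.58 ± 0.076), CYP24A1 9.74-fold (3.28 ± 0.11) and ID2 7.77-fold (2.96 ± 0.079). FLG was 7.08-fold (log2 change -2.82 ± 0.16, adjusted p = 1.23e-07) lower with MEK inhibition, HAS3 at least 4.86-fold, the mTOR-binding inhibitor DEPTOR 3.83-fold (-1.94 ± 0.12) and PHLDA1 3.67-fold (-1.87 ± 0.082). Of 19 TGF-beta and SMAD targets, 16 were higher with MEK inhibition and 3 did not pass (median 1.26, adjusted p = 3.08e-18), and ID3 and PMEPA1 differed by 2.26 ± 0.079 and 1.91 ± 0.078. Of 16 mesenchymal genes, 8 were higher, 1 lower and 7 did not pass (over the list alone, 9 higher and 1 lower; median 0.55, adjusted p = 3.57e-06). The collagen COL5A1 had 2.11 ± 0.10 and CDH2 1.65 ± 0.078. Actin and SRF targets (median 0.23, adjusted p = 3.06e-05; 10 of 20 higher, 14 over the list alone), focal adhesion and integrin genes (median 0.21, adjusted p = 0.000318; 10 of 23 higher and 1 lower, 11 and 1 over the list alone) and epithelial junction genes (median 0.22, adjusted p = 0.00256; 12 of 24 higher and 1 lower, 13 and 1 over the list alone) were higher too, with TPM1 at 0.76 ± 0.083, ITGB6 at least 4.64-fold higher and DSP at 0.46 ± 0.072. The cell division lists were lower with MEK inhibition: 34 genes of G2/M and mitosis were lower in 33 cases (median -0.68, adjusted p = 2e-23) and 36 genes of G1/S and DNA replication in 31 (34 over the list alone; median -0.53, adjusted p = 3.19e-18), with CCNA2 at -0.69 ± 0.065 and CDC45 at -0.68 ± 0.073. ERK output (median -0.65, adjusted p = 8.48e-09; 16 of 25 lower, 1 higher, and 16 and 2 over the list alone), ribosome biogenesis and MYC targets (median -0.39, adjusted p = 2.8e-10; 21 of 31 lower, 26 over the list alone) and DNA repair (median -0.47, adjusted p = 8.57e-09; 16 of 21 lower, 1 higher) were lower as well, with DUSP6 at -1.73 ± 0.17, FOSL1 at -1.70 ± 0.15, NOLC1 at -0.64 ± 0.063 and EXO1 at -0.67 ± 0.085.

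Among single genes, ETV4 (-1.31 ± 0.13), ETV5 (-1.64 ± 0.12), SPRY4 (-0.85 ± 0.10), CCND1 (-0.65 ± 0.068) and EGR1 (-1.0 ± 0.089) were lower with MEK inhibition. CDKN1B (-0.017 ± 0.11), INSR (-0.045 ± 0.14), NF1 (0.059 ± 0.17) and ALDH1A1 (-0.030 ± 0.10) did not pass. Nor did MYC (-0.025 ± 0.090), which passed with the mean of its probes (-0.23), BCL2L11 (-0.29 ± 0.11), which passed with the replicate block (adjusted p = 0.0387), CDKN1A (0.29 ± 0.12), which passed without Src inhibition replicate 1 (0.39), and MAP2K1 (-0.16 ± 0.076), which passed without Src inhibition replicate 3 (-0.22). SRC had 0.39 ± 0.081 (adjusted p = 0.00349), a call that ended with the mean of its probes (0.20). Another 9 lists passed with the preset correlation only. Interferon response (median 0.29, adjusted p = 9.04e-06; adjusted p = 0.0506 with an estimated correlation), lysosome and autophagy (median 0.19, adjusted p = 0.00143; adjusted p = 0.0506 with an estimated correlation), YAP and TEAD targets (median 0.25, adjusted p = 0.00156; adjusted p = 0.0511 with an estimated correlation) and antigen presentation (median 0.24, adjusted p = 0.00523; adjusted p = 0.0803 with an estimated correlation) were among them. So were glycolysis and hypoxia (median 0.17, adjusted p = 0.008; adjusted p = 0.102 with an estimated correlation), cholesterol synthesis (median 0.15, adjusted p = 0.0235; adjusted p = 0.0613 with an estimated correlation), ER chaperones (median 0.14, adjusted p = 0.0494; adjusted p = 0.253 with an estimated correlation), oxidative phosphorylation (median -0.10, adjusted p = 0.0494; adjusted p = 0.102 with an estimated correlation) and NRF2 targets (median -0.13, adjusted p = 0.0241; adjusted p = 0.0672 with an estimated correlation), whose median was -0.084 without Src inhibition replicate 3 and -0.094 without MEK inhibition replicate 1, which ended the call. The calls of cholesterol synthesis (0.077, adjusted p = 0.0568) and ER chaperones (0.11, adjusted p = 0.146) ended with median centring, the second also without any 1 control, MEK inhibition replicate 2 or 3 or Src inhibition replicate 2 or 3 (0.12 to 0.16). That of oxidative phosphorylation ended with the replicate block (-0.10) and without any 1 control, MEK inhibition replicate 1 or 3 or Src inhibition replicate 1 or 2 (-0.11 to -0.087). Over all genes 3560 (27.0%) passed, 1827 higher and 1733 lower with MEK inhibition (1498 and 2147 with median centring), 145 and 53 of them by at least 2-fold.

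The interaction asks whether the change with both inhibitors differed from the sum of the log2 changes with each. For VTCN1 the combination lay below that sum (interaction -3.29 ± 0.15, adjusted p = 1.04e-07), which predicts a level of 14.8, just under the highest on any array, and MMP7 (-3.11 ± 0.16), KRT13 (-3.0 ± 0.11) and the retinoic acid-responsive RARRES1 (-2.71 ± 0.12) also had negative interactions. The combination lay above the sum for ESM1 (interaction 3.19 ± 0.11, adjusted p = 1.86e-08), the beta-defensin DEFB103A (2.15 ± 0.32), DENND2A (1.80 ± 0.17) and FAM180A (1.65 ± 0.17). For ESM1 and DEFB103A the sum predicts levels (3.14 and 4.41) under the lowest detected in the combination (5.06, a mean over its arrays), so these sizes cannot be read; the combination lay 2.39-fold and 2.81-fold above that level. TGF-beta and SMAD targets lay below the sum in 12 of 19 genes and above it in 1 (over the list alone, 14 and 2; median -0.59, adjusted p = 4.58e-08). BAMBI had -2.22 ± 0.11, ID2 -1.74 ± 0.11 and ID1 -1.39 ± 0.11. G2/M and mitosis genes lay below the sum in 16 of 34 and above it in 1 (24 and 1 over the list alone; median -0.40, adjusted p = 2.81e-10), and G1/S and DNA replication genes below it in 9 of 36 (13 over the list alone; median -0.25, adjusted p = 4.68e-05). KIF4A had -0.73 ± 0.11 and RRM2 -1.14 ± 0.12, so that both fell further in the combination than the sum. Interferon response genes lay below the sum in 11 of 33 (15 over the list alone; median -0.32, adjusted p = 5.58e-07), with the antiviral gene OASL at -1.98 ± 0.14, and NF-kB and inflammatory cytokines in 6 of 21 (10 over the list alone; median -0.33, adjusted p = 1.37e-05). CCL2 had -1.36 ± 0.13.

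Epithelial junction genes lay below the sum in 8 of 24 (10 over the list alone; median -0.26, adjusted p = 1.87e-05), actin and SRF targets in 8 of 20 (10 over the list alone; median -0.36, adjusted p = 6.96e-05) and antigen presentation genes in 5 of 16 (9 over the list alone; median -0.41, adjusted p = 0.00011). CLDN1 had -0.95 ± 0.11, TAGLN -1.14 ± 0.17 and HLA-C -0.63 ± 0.14. Ribosome biogenesis and MYC targets lay above it as a list (median 0.14, adjusted p = 0.00721), although 1 of 31 genes, the nucleolar FBL (0.45 ± 0.13), passed over all genes and none over the list alone; that call ended without any array but Src inhibition replicates 1 and 3 (0.42 to 0.48). For 2 lists the call held with the preset correlation only: cholesterol synthesis (median -0.12, adjusted p = 0.0248; adjusted p = 0.0678 with an estimated correlation) and lysosome and autophagy (median -0.17, adjusted p = 0.0354; adjusted p = 0.183 with an estimated correlation). The second of these calls also ended with median centring (-0.025) and without control replicate 1, MEK inhibition replicate 2, Src inhibition replicate 1 or 2, or combination replicate 3 (-0.18 to -0.17). ERK output did not pass (median 0.15, adjusted p = 0.183; 3 genes above and 3 below the sum, 6 and 4 over the list alone), but did without background correction (0.15) and in the authors' value table (0.097). Immediate early genes passed without control replicate 3 (-0.18), MEK inhibition replicate 1 (-0.24) or combination replicate 1 (-0.22), and ribosomal proteins without control replicate 3 (0.080), MEK inhibition replicate 1 (0.078) or combination replicate 3 (0.092) and in 4 alternatives with all arrays (0.068 to 0.23). Without the filter on dim probes immediate early genes (-0.18) and DNA repair (-0.16) passed too. DUSP6 (0.30 ± 0.24), SPRY4 (-0.0040 ± 0.15), CCND1 (0.15 ± 0.10), MAP2K1 (0.092 ± 0.11), SRC (-0.15 ± 0.12), BCL2L11 (-0.16 ± 0.16), CDKN1B (0.084 ± 0.16), NF1 (-0.25 ± 0.24) and ALDH1A1 (-0.19 ± 0.14) had interactions that did not pass (SPRY4 and ALDH1A1 on probes detected on no combination array), whereas EGR1 (-0.79 ± 0.13) and CDKN1A (-0.83 ± 0.17) lay below the sum. FOSL1 (0.64 ± 0.21), which passed without Src inhibition replicate 3 (0.83), ETV5 (0.48 ± 0.16), ETV4 (0.38 ± 0.18) and MYC (0.35 ± 0.13) did not pass, but did in 7, 4, 3 and 3 alternatives. INSR had -0.69 ± 0.20 (adjusted p = 0.0477), a call that 16 of 21 alternatives ended, at -0.76 to -0.16, among them leaving out any array but MEK inhibition replicate 3 and combination replicate 1.

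Over all genes 1265 (9.60%) had an interaction that passed, 395 positive and 870 negative, 38 and 140 of them by at least 2-fold, and with median centring 619 were positive and 598 negative. Of 1789 genes that rose with each inhibitor, 479 had an interaction that passed, 465 of them below the sum, and the median change was 0.93 in the combination against a median sum of 1.19. Of 1310 genes that fell with each inhibitor, 227 had an interaction that passed, 188 of them above the sum, and the medians were -0.86 and -1.06. These 1789 and 1310 genes (1455 and 1847 with median centring) outnumbered those expected of independent lists, 549 and 390, and 104 moved oppositely. Both comparisons share the 3 control arrays, which can add overlap. Across genes the changes had r of 0.761, against 0.501 in 100 simulations with no changed gene, and 78.7% against 66.7% shared sign. Their covariance, 0.139 against 0.00721, argues against shared controls as its main source. Genes are not independent in these counts.

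**Figure D5:**
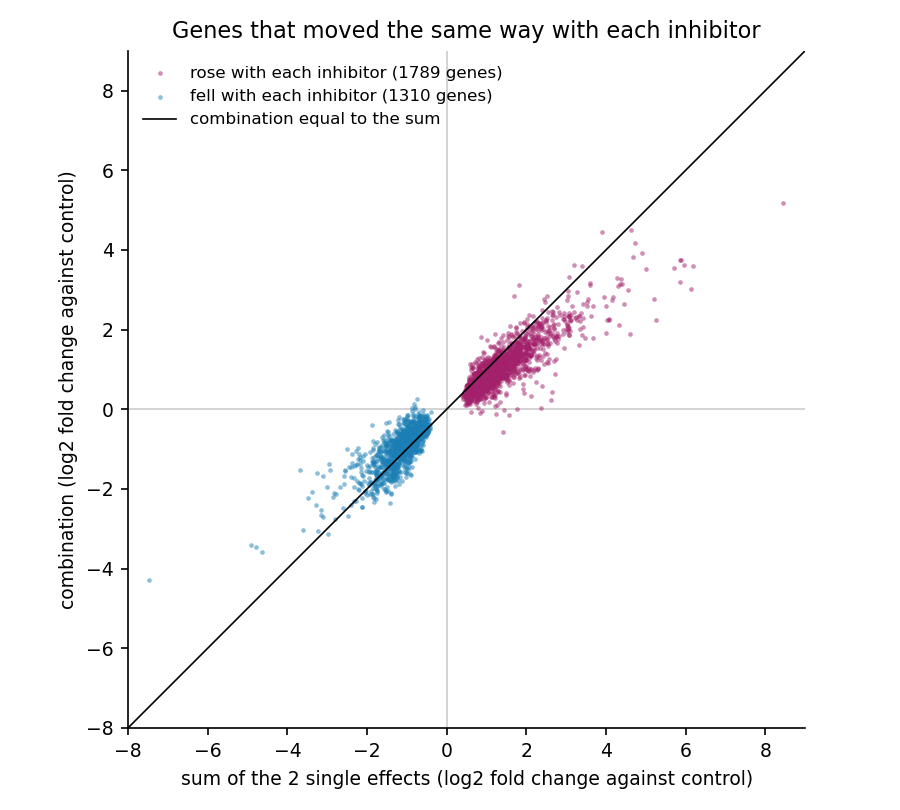
Each point is a gene, with the sum of its log2 changes under MEK inhibition and under Src inhibition on the horizontal axis and its log2 change in the combination on the vertical axis; the line marks equality. Coloured genes rose (1789) or fell (1310) with each inhibitor.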

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

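The tests of saturation and of the floor, and both tests on Src inhibition replicate 3, were chosen only after the result was seen.

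Interactions that passed are those whose change with both inhibitors differed from the sum of the changes with each; for ESM1 and DEFB103A that sum lies under the lowest detected level. They were 1265 genes, 11 lists and the 8 named genes with the largest values: VTCN1 (-3.29), MMP7 (-3.11), KRT13 (-3.0), RARRES1 (-2.71), ESM1 (3.19), DEFB103A (2.15), DENND2A (1.80) and FAM180A (1.65). The sizes for RARRES1 and FAM180A depend on the probe. The list medians were -0.59 for TGF-beta and SMAD targets, -0.41 for antigen presentation, -0.40 for G2/M and mitosis, -0.36 for actin and SRF targets, -0.33 for NF-kB and inflammatory cytokines, -0.32 for interferon response, -0.26 for epithelial junctions, -0.25 for G1/S and DNA replication, -0.17 for lysosome and autophagy (adjusted p = 0.183 with an estimated correlation; -0.025 with median centring), -0.12 for cholesterol synthesis (adjusted p = 0.0678 with an estimated correlation) and 0.14 for ribosome biogenesis and MYC targets. Probes without a gene symbol, which no comparison used, also differed from control: of 6649 detected, 1440 passed with MEK inhibition (618 higher, 822 lower), 545 with Src inhibition (265 higher, 280 lower) and 2313 in the combination.

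Genes that rose with each inhibitor rose less in the combination than the sum of the single changes. Noise shared by the choice of genes and the interaction was tested by choosing genes on 1 array per group and measuring the interaction on the others: the median stayed between -0.31 and -0.29 over the 3 choices, which argues against it. Saturation of bright probes was tested on genes whose 4 levels and predicted level all lay between 8 and 12 on the log2 scale, where the medians were -0.32 to -0.29, against it. Normalization was tested under 4 other scalings, where the median nearest 0 was -0.13 (in the authors' value table), against it as the whole cause. No biological explanation was tested, so the cause stays open.

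For genes that fell with each inhibitor the smaller change in the combination held over all levels (0.15 to 0.18 on the held-out arrays), but among genes at mid-range levels the medians were 0.016 to 0.095. The floor of dim probes may therefore account for it, since the value farthest from 0 at mid range was 0.095.

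Src inhibition replicate 3 lay apart from the other arrays of its group, with a residual SD of 0.191 against 0.109 to 0.137 on the other arrays. A dim or sparsely filled array was argued against, since 0 of 3 measures (detected probes, mean signal and median beads) lay outside the range of the other 11 arrays. RNA of another treatment group was argued against too, since the differences between group means explained 8.89% of its deviation across genes. No biological explanation was tested, and a difference in culture or handling stays open.

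Other splits of the same arrays were counted for each comparison. In each of the 6 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many genes as observed, the highest other split giving 0 genes (1 for MEK inhibition against Src inhibition), and 10 splits are too few for a share under 0.05. The real counts were 6478, 3796, 8008, 3898, 5777 and 3560. For the interaction, 2 of 100 regroupings of the 12 arrays, the real one included, gave 1265 genes or more, and the highest other gave 2738. Regroupings mix the treatments, which raised the median residual SD to 0.193 to 0.256 against 0.132 with the real groups, and treatment differences enter them as an interaction. The count therefore does not say whether chance can be excluded, and the 2738 genes point to the structure of the samples.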

How the results depend on the processing

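The overlap's alternatives were chosen after the result was seen, and the others planned. In all, 696 values no longer passed, 409 came to pass, 6 passing values changed sign and 18 summary counts moved by over 1.5 times. The other 31290 include counts, and only passing values were checked for sign. Requiring a fold of at least 2 leaves, by construction, 777, 224, 1636, 204, 468, 178 and 198 genes in the 7 comparisons, in the order first listed. With array weights the interaction count was 2030; the cause was not tested, though Src inhibition replicate 3 had the weight 0.191. An estimated correlation widens a list's assumed spread. Camera then called 8 lists in the combination against control, 5 and 7 against MEK and Src inhibition and 10 between the single treatments. Limma's fry tests each list against no change, not other genes. It called 30, 27 and 30 lists against control, 26 and 27 in the combination against MEK and Src inhibition, and 25 in the interaction. With the mean of probes, values that had passed changed sign for MCL1 (-0.019 with MEK inhibition, -0.29 in the combination against control and -0.048 against Src inhibition), RPL13 (-0.53 and -0.14 in the last 2) and BCL2L1 (-0.054 in the combination against MEK inhibition), where probes of 1 gene differ. The cause was not tested.

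Leaving out each array in turn gave 5614 to 7124 genes with MEK inhibition, 2839 to 4006 with Src inhibition, 7316 to 8517 in the combination, 2873 to 4763 and 4998 to 5930 in the combination against MEK and Src inhibition, 901 to 1810 in the interaction, 2632 to 3810 between the single treatments and 2361 to 3360 in the overlap, each highest without Src inhibition replicate 3. Lists called were 13, 17 to 20, 14, 14 to 15, 8 to 11, 10 to 13 and 17 to 19 in that order of comparisons. Medians with MEK inhibition, Src inhibition and the combination were -0.88 to -0.75, -0.36 to -0.28 and -1.10 to -1.04 for ERK output, -0.82 to -0.77, -0.27 to -0.20 and -1.37 to -1.30 for G1/S and DNA replication, and -1.01 to -0.97, -0.34 to -0.30 and -1.74 to -1.67 for G2/M and mitosis. In the authors' value table, which compresses low values, the ERK output medians were smaller, at -0.44, -0.22 and -0.57. With the replicate number as a block the counts were 6387, 3651, 7912, 3701, 5632, 1099 and 3359, and the overlap 2986. Fitting only the groups compared gave fewer genes for the Src inhibition group (2858, 4646, 2664) and more otherwise (7111, 8208, 4229). No scaling moved a comparison's median over genes by over 0.1. Median centring turned the balance of rises and falls in all but the combination against Src inhibition. No slide is given, so that alternative was not run. Signal over background limits the dim genes, with 45.3% to 47.7% of probes detected.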

Other observations

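The test of aryl hydrocarbon receptor targets was planned before their values were seen, and the families of small RNAs and histones were chosen only after the result was seen.

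Small nuclear and nucleolar RNAs and histone genes are given here as counts, with no test against other genes, of which 49.2% passed with MEK inhibition, 28.8% with Src inhibition and 60.8% in the combination. The values are probe signals from amplified cRNA, and whether they follow the levels of the mature RNAs was not tested. All 5 spliceosomal small nuclear RNA genes measured (RNU1, RNU2 and RNU4) rose with MEK inhibition and in the combination and 4 rose with Src inhibition, with median log2 changes of 1.26, 1.64 and 0.58. RNU4-1 changed by 2.41 with MEK inhibition, 0.64 with Src inhibition and 2.34 in the combination, and the transcription regulator RN7SK by 1.47, 0.90 and 2.05. Of 75 H/ACA small nucleolar RNAs, which guide pseudouridylation, 43 fell and 1 rose with MEK inhibition, 31 fell and 1 rose with Src inhibition, and 41 fell and 7 rose in the combination (medians -0.45, -0.30 and -0.37). Of 82 C/D small nucleolar RNAs 33, 17 and 24 fell and 6, 6 and 23 rose, and of 16 small Cajal body RNAs 9, 7 and 6 fell and 2, 1 and 3 rose. Replication-dependent histone genes fell in 31, 25 and 27 of 42 cases and rose in 3, 2 and 6 (medians -0.61, -0.48 and -0.65). The sign of these medians held under each scaling. The spliceosomal medians lay at 1.08 to 1.26, 0.49 to 0.58 and 1.49 to 1.64 over the scalings, with MEK inhibition, Src inhibition and the combination in turn, but the H/ACA medians moved more, -0.45 to -0.12, -0.33 to -0.096 and -0.37 to -0.11, and those of the histones -0.63 to -0.17, -0.52 to -0.14 and -0.65 to -0.16.

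CYP1A2 rose in the treated groups, by 3.45 with MEK inhibition, 2.73 with Src inhibition and 3.60 in the combination, and it is a target of the aryl hydrocarbon receptor. The hypothesis that the inhibitors act on this receptor was tested on its other targets: 4 of 5 measured rose in the combination, CYP1A1 (2.59), CYP1B1 (3.15), NQO1 (0.96) and ALDH3A1 (0.98), while TIPARP had 0.17 (adjusted p = 0.0728) and AHRR and UGT1A6 were not measured. In the single treatments CYP1A1 rose by 1.46 and 1.69, CYP1B1 by 2.11 and 2.24 and NQO1 by 0.70 and 0.70 with MEK and Src inhibition, while ALDH3A1 (0.098 and 0.22) and TIPARP (-0.099 and 0.019) did not pass. Receptor activity may therefore be part of the response, but NQO1 is also an NRF2 target and neither inhibitor is named, so the origin stays open.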
